A study of Mus musculus with 12 samples.

How the data were processed

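RNA was sequenced in bulk from the hearts of wild-type C57BL/6J mice, an inbred laboratory strain, in 12 libraries: 3 each from exercised females, sedentary females, exercised males and sedentary males. Per the labels' protocols, exercised mice ran on a treadmill at 1 km/h for 45 min a day on 5 days a week for 6 weeks, and sedentary mice of the same age stayed in their cages. The hearts were kept in a preservative and libraries were made by a commercial service. How each heart was trimmed, the kit, whether it keeps strand, and any batch are not given in the sources used here. Each library is taken as 1 animal, which the labels do not state in words, so p-values measure the spread between libraries. Groups share no replicate numbers in the labels, and no pairing was used.

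The deposited table holds counts of reads per gene, which the authors made before any normalization: per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.5.2b to the mouse genome GRCm38 and counted with featureCounts of Subread 1.5.2. The annotation release and the strand setting of the counting are not given in the sources used here, so values of genes that overlap an antisense gene are uncertain. So are those of genes with close copies, such as ribosomal proteins, ferritin chains, cytochrome c and globins. The table has 55401 rows. Of their identifiers, 54349 matched the GRCm38 annotation used here with the version number, and 55141 rows have a symbol. Coordinates are those of that annotation, counted from 1.

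Total counts ran from 22204349 to 32566240 per library. The 37 rows of the mitochondrial genome were 0 in 11 libraries and held 27.3% of the counts in female sedentary 2. The filter removed them, and only the settings without a filter and DESeq2 took them in. Without them, the highest total was 26607844. Nuclear pseudogene copies of mitochondrial genes, which were among the most abundant rows, stayed in the tables. They are counted but not named. Libraries of 1 group differed by far more than sampling noise: the chi-square per degree of freedom ran from 9.33 to 34.7 over the pairs, so each library counts as 1 replicate.

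Counts were analysed with edgeR 4.0.16 in R 4.3.3. The filterByExpr filter kept 16213 genes, and libraries were scaled with the trimmed mean of M-values. One group-means model was fitted to all 12 libraries, with 8 residual degrees of freedom, and 6 contrasts were tested with edgeR's quasi-likelihood test with robust spread estimates and Benjamini-Hochberg adjustment at 0.05. These were exercise in females, exercise in males, the difference between these effects, their average, and females against males in sedentary and in exercised hearts. Fold changes are on the log2 scale with their standard error (SE). Levels are counts scaled to library size (CPM) with the standard deviation (SD).

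The contrasts, alternatives, rule for named genes and 49 gene lists were fixed before the data were examined. Of the lists, 42 had 5 or more tested members and were tested with camera of limma 3.58.1, which compares a list with all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment. The X-linked list was a check of the labels and is not counted among the calls. The same test with a correlation estimated per list, and fry, which asks whether a list's genes move on balance 1 way, were run beside it. Member genes were also adjusted over the list alone.

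Genes were named by rule. In each exercise contrast these were the 10 of smallest p in each direction among genes that passed without overlap between groups or, where fewer than 5 passed, the 5 of smallest unadjusted p. To these came up to 4 members of smallest p of each called list and a panel of 26 genes of heart load, conduction, matrix, metabolism and clock, whatever their result. In the sex contrasts the sex chromosome lists, 6 genes in each direction and list members were taken. A gene named in 1 sex has its value given in the other where the sexes are compared. The text names a part of these genes, some are not reported here, and it says where a gene was chosen after its values were seen.

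The other settings fixed in advance were 2 other scalings (RLE and upper quartile), no filter and a stricter filter (CPM above 1 in 3 libraries), DESeq2 1.42.0, limma's voom with sample weights, spread estimates without robustness, 1 surrogate variable from sva 3.50.0, an adjusted p of 0.1, fits of only the groups compared, and each library left out in turn. For lists, these were RLE, the estimated correlation, ranks and each library left out. Another 4 were added after the data were seen: the mean of 5 atrial genes as a covariate and the 9 libraries with few atrial transcripts, both because 3 female libraries held such transcripts, pseudogenes left out, and edgeR's bias-adjusted test without a filter, because the planned fit without a filter broke down. Exact two-sided permutation tests were used for 25 measures of composition. With 3 libraries against 3, the smallest p such a test can give is 0.1. Permuting within both sexes, it is 0.005, or 0.125 for 1 measure adjusted over the 25, so 1 measure alone could not pass.

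The fit was tested on simulated counts of 16213 genes with 200 genes changed, 50 at each fold of 1.25, 1.5, 2 and 4. For exercise in females, with 16063 genes after filtering, 10%, 38%, 60% and 84% of the changed genes were called at these folds. For exercise in males, with 16047 genes, the shares were 6%, 38%, 64% and 76%. For the sex difference of the exercise effect, with 16058 genes, they were 0%, 10%, 54% and 80%. For the average over the sexes, also with 16058 genes, they were 28%, 58%, 74% and 94%. For the sex difference in sedentary hearts, with 16068 genes, they were 4%, 32%, 76% and 88%, and for that in exercised hearts, with 16045 genes, 6%, 40%, 74% and 90%. In each, 4 to 9 unchanged genes were called. With nothing changed and genes simulated as independent, camera called 0 of 42 lists in each contrast over 16046 genes, and it called the fatty acid oxidation list when that was raised 1.25-fold in females. Genes in real hearts are not independent, and the report gives the number of lists called with other groupings of the same libraries.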

Results

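Hearts of C57BL/6J mice were sequenced after 6 weeks of treadmill running or of cage life, with 3 libraries for each sex and condition. The series asks which transcripts exercise changes and whether the sexes differ in this. The median SE of a log2 fold change was 0.14 for each comparison of 3 libraries with 3. The labels of sex held in all 12 libraries. Xist, the RNA that silences an X chromosome in females, stood at 166 ± 23.8 CPM in sedentary and 158 ± 18.2 CPM in exercised females, against 0.926 ± 0.604 and 1.09 ± 0.38 CPM in the males (SD, n = 3 each). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were carried by the male libraries, and the counts per library in females came to 0.788% of those in males for exercised and 0.131% for sedentary libraries.

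The hearts differed in what tissue they held. Myl7, the atrial myosin light chain, reached 107 CPM in female exercised 2, 65.6 in female sedentary 1 and 23.0 in female sedentary 2, and lay between 0.41 and 2.33 CPM in the other 9 libraries. Sln, an atrial inhibitor of the calcium pump, stood at 43.6, 25.4 and 7.9 CPM in the same 3 libraries and at no more than 1.04 CPM elsewhere. Haemoglobin transcripts were high in 2 of these 3: Hbb-bs was at 968 and 452 CPM in female sedentary 1 and 2, with 77.2 CPM in female exercised 2 and 2.07 to 24.1 CPM in the others. Adipoq and Cfd, made by fat cells, reached 10.1 and 68.0 CPM in female exercised 2. Over 25 measures of composition and handling, exercised and sedentary libraries were compared by exact permutation within both sexes, with 400 assignments. The smallest p was 0.035, for the mean of the immediate early genes, and the smallest Benjamini-Hochberg adjusted p 0.781. The first principal component of the log2 CPM values held 36.8% of the variance. Males lay at or above 8, the 3 libraries with atrial transcripts from -27.8 to -17.18 and the other females from -7.49 to -0.38. On the second, female sedentary 2 stood apart at -23.51.

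**Figure D1:**
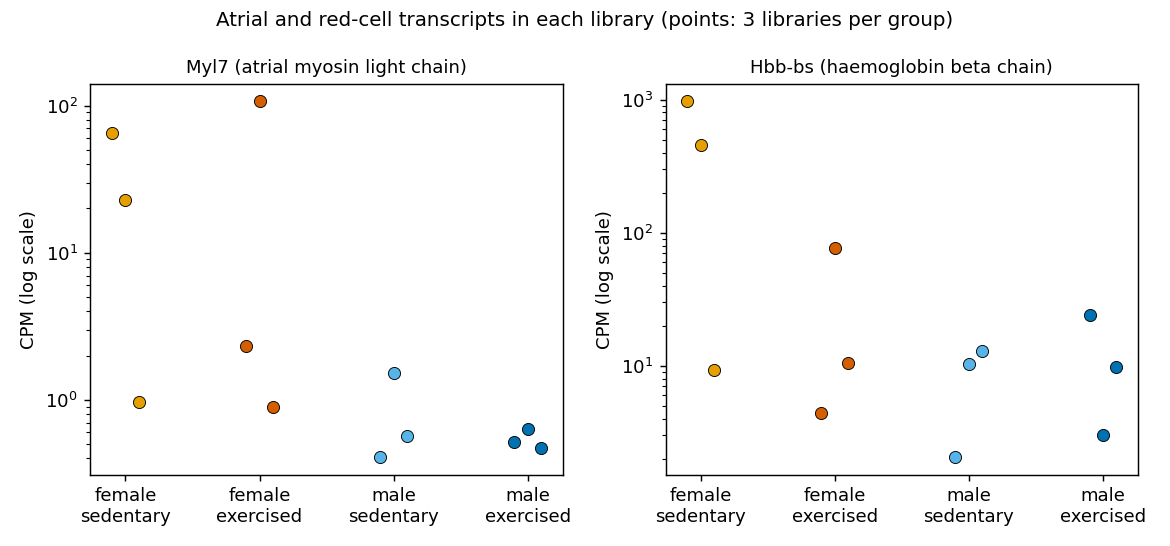
Levels of Myl7 (left) and Hbb-bs (right) in each library, in CPM on log axes, with 1 point per library and 3 libraries per group. Female exercised 2 and female sedentary 1 and 2 lie between 23.0 and 107 CPM for Myl7, and the other 9 lie between 0.41 and 2.33 CPM.

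In females no gene passed for exercise, and the calls of the lists of cardiac load, below 0, and fat burning, above 0, did not hold with an estimated correlation (adjusted p = 0.533 and adjusted p = 0.523 with an estimated correlation). Myh7, the slow myosin heavy chain of the fetal and loaded heart, was at 811 ± 126 CPM in exercised and 1623 ± 310 CPM in sedentary hearts (SD, n = 3), a log2 difference of -1.0 ± 0.25 (SE). Nppa, the atrial natriuretic peptide, was at 76.0 ± 19.0 against 222 ± 26.3 CPM (-1.55 ± 0.42). Ankrd1, a stretch-responsive sarcomere protein, differed by -0.55 ± 0.21. Of 14 tested genes of the cardiac stress and fetal list, 13 lay below 0, with a median of -0.17, and 2 passed when adjusted over the list alone. Of 27 genes of fatty acid oxidation, 26 lay above 0, with a median of 0.17. Etfdh, which passes electrons from fatty acid oxidation to ubiquinone, was at 0.28 ± 0.07. Cpt2, of the carnitine shuttle, at 0.30 ± 0.09, Slc25a20, the carnitine carrier, at 0.27 ± 0.09, and Eci1 at 0.17 ± 0.06.

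The respiratory chain and the citric acid cycle lay on the same side in females. Of 48 nuclear genes of oxidative phosphorylation 45 were above 0 (median 0.08), with Cycs, cytochrome c, at 0.24 ± 0.07 and Atp5a1, a subunit of ATP synthase, at 0.13 ± 0.05. In the citric acid cycle list 20 of 22 were above 0 (median 0.10), Mdh2 at 0.14 ± 0.06 and Cs, citrate synthase, at 0.12 ± 0.05. Immediate early genes, which answer acute stimuli within the hour, were above 0 in 23 of 24 cases (median 0.40), with Jun at 0.41 ± 0.16 and Egr3 at 0.70 ± 0.28. Inflammatory and acute phase genes were above 0 in 19 of 21 (0.42), among them Serpina3n at 0.61 ± 0.21 and Ccl2 at 0.77 ± 0.33. All 16 macrophage markers were above 0 (0.23), with Lyve1 at 0.42 ± 0.19 and Cd68 at 0.41 ± 0.19, as were 24 of 26 genes of oxidative stress defence (0.10). Extracellular matrix genes lay below 0 in 29 of 34 cases (-0.11), with Col8a1 at -0.27 ± 0.11, and so did 24 of 28 interferon genes (-0.14), with Ifit2 at -0.29 ± 0.13 and Xaf1 at -0.30 ± 0.15. Postn, a matrix protein of activated fibroblasts, stood at 35.7 ± 0.66 CPM in exercised and 48.5 ± 5.05 CPM in sedentary females (-0.44 ± 0.12).

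Camera with the preset correlation called 15 of the 42 lists in females, 9 higher and 6 lower. Its adjusted p was 1.99e-13 for fatty acid oxidation and 8.19e-09 for oxidative phosphorylation (adjusted p = 0.523 with an estimated correlation for both). It was 2.91e-07 for the immediate early genes (adjusted p = 0.533 with an estimated correlation), 2.68e-06 for the citric acid cycle (adjusted p = 0.278 with an estimated correlation) and 0.000336 for the cardiac stress list (adjusted p = 0.533 with an estimated correlation). Oxidative stress defence and macrophage markers had 5.78e-05 and 0.000134 (adjusted p = 0.523 and adjusted p = 0.533 with an estimated correlation). None of the 15 calls held with an estimated correlation, and the citric acid cycle alone was called by fry (adjusted p = 0.0248). These 7 lists kept their call without any 1 library, and the other 8 did not. Matrix genes (0.000454; adjusted p = 0.533 with an estimated correlation), interferon genes (0.000483; adjusted p = 0.6 with an estimated correlation) and inflammatory genes (0.000781; adjusted p = 0.533 with an estimated correlation) lost theirs without female exercised 1, at 0.051, 0.0774 and 0.0516. In the 9 libraries with few atrial transcripts, oxidative phosphorylation (median 0.02, adjusted p = 0.606), oxidative stress defence (0.06, adjusted p = 0.301) and matrix genes (-0.07, adjusted p = 0.0603) were not called. Medians that moved by more than 1.5 times with 1 library left out ran from -0.34 to -0.10 for cardiac stress, from 0.24 to 0.46 for immediate early, from -0.20 to -0.07 for matrix and from -0.22 to -0.08 for interferon genes.

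Markers of blood and valve differed between libraries of 1 female group. As a mean log2 CPM, erythroid markers were at 7.22 and 6.28 in female sedentary 1 and 2, 1.53 in female sedentary 3 and 1.36, 4.10 and 1.93 in exercised females (exact permutation p = 0.3, and p = 0.4 for valve markers). All 7 erythroid markers lay below 0 (median -3.96, 6 passing when adjusted over the list alone), Hbb-bt at -4.01 ± 1.54, with a camera adjusted p of 0.000134 (adjusted p = 0.533 with an estimated correlation). Without female sedentary 1 this became 0.123. Of 7 valve and cartilage markers 6 lay below 0 (-0.82), with Chad at -2.14 ± 0.90 and Fmod at -0.82 ± 0.34 (camera adjusted p = 0.022; adjusted p = 0.533 with an estimated correlation). That call was lost without female exercised 2 (0.15) or 3 (0.375) and without female sedentary 1 (0.35) or 2 (0.0727). The weakest calls were the PPAR-responsive genes (14 of 19 above 0, 0.12), the glucocorticoid-responsive genes (17 of 20, 0.20, Fkbp5 at 0.38 ± 0.29 and Sgk1 at 0.27 ± 0.15) and the ribosomal proteins (25 of 30 below 0, -0.03, Rps19 at -0.17 ± 0.07). Their camera adjusted p was 0.014, 0.0403 and 0.042 (adjusted p = 0.63, adjusted p = 0.782 and adjusted p = 0.938 with an estimated correlation). The first was lost without female exercised 1 (0.265) or 3 (0.0685) and without female sedentary 2 (0.0505) or 3 (0.44), the second without the same libraries (0.974, 0.315, 0.219 and 0.124). The ribosomal call was lost without female exercised 3 (0.897), female sedentary 1 (0.0725) or 3 (0.789, with the median at 0.03), male exercised 2 (0.0516) or male sedentary 1 (0.0548). The 9 libraries with few atrial transcripts ended the erythroid and valve calls (-0.22 and 1.03, adjusted p = 0.397 and adjusted p = 0.342), and the atrial score as a covariate the glucocorticoid-responsive one (0.15, adjusted p = 0.0967). Across fits that each leave out 1 library, these medians moved by more than 1.5 times and ran from -5.99 to -2.92 for erythroid, from -1.01 to -0.25 for valve, from 0.01 to 0.22 for PPAR-responsive, from 0.04 to 0.44 for glucocorticoid-responsive and from -0.10 to 0.03 for ribosomal genes.

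No gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment for exercise in females: 0 of 16213, with 637 (3.93%) at an unadjusted p under 0.05 and a smallest adjusted p of 1. In 1587 genes (9.8%) the 3 exercised libraries did not overlap the 3 sedentary ones, where chance gives 10%. Voom called 0. DESeq2 called 1, the Y-linked Ddx3y, from 54 counts in exercised and 6 in sedentary females. Of the genes of smallest p, Dpysl3, a cytoskeletal regulator, was at -0.44 ± 0.10, Shtn1 at -0.56 ± 0.15, Scgb1c1 at -0.97 ± 0.25, Fgf6, a growth factor of muscle, at -1.50 ± 0.35 from 0.678 and 1.92 CPM, and Vwa8, a mitochondrial ATPase, at 0.28 ± 0.08. Eif4ebp1, a repressor of translation, passed without female exercised 3 (-0.93 ± 0.10, adjusted p = 0.00474), and Ppbp, a platelet chemokine, without female sedentary 3 (-3.47 ± 0.43, adjusted p = 0.0243); both were named after their values were seen. Other divisions of these 6 libraries called at most 12 lists.

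The rest of the fixed panel in females held no gene past the test. Nppb, the brain natriuretic peptide, was at -0.74 ± 0.44, Acta1, skeletal actin, at -0.16 ± 0.52, and Fos at 0.50 ± 0.36. Among genes of conduction and calcium, Gja1 and Gja5, connexins, were at -0.03 ± 0.12 and 0.07 ± 0.15, and the potassium channel genes Kcnd2, Kcnip2 and Kcnj2 at 0.30 ± 0.20, 0.02 ± 0.11 and 0.14 ± 0.30. Ryr2, the calcium release channel, was at 0.12 ± 0.10, Atp2a2, the calcium pump, at 0.14 ± 0.07, and its inhibitor Pln at 0.02 ± 0.09. The collagens Col1a1 and Col3a1 were at -0.06 ± 0.11 and -0.03 ± 0.20. Cebpb and Cited4, linked to exercise growth of the heart, were at 0.42 ± 0.50 and 0.10 ± 0.23, and the metabolic genes Ppargc1a, Pdk4 and Ucp3 at -0.05 ± 0.18, 0.13 ± 0.52 and 0.09 ± 0.61. The clock genes Dbp, Per2 and Arntl were at 0.26 ± 0.80, -0.11 ± 0.43 and -0.16 ± 0.58, and Hspa1a, a heat shock protein, at -0.03 ± 0.53. Of 68 gene values in females 35 moved by more than 1.5 times with 1 library left out. Those that did not turn ran from 0.46 to 0.86 for Egr3, 0.40 to 0.79 for Serpina3n, 0.23 to 0.55 for Lyve1, 0.22 to 0.53 for Cd68, -0.38 to -0.18 for Xaf1, -2.70 to -1.27 for Chad, 0.03 to 0.65 for Fkbp5, 0.12 to 0.44 for Sgk1, -0.93 to -0.49 for Nppb and 0.18 to 0.43 for Kcnd2. The rest ran from 0.02 to 0.18 for Ryr2, 0.08 to 0.17 for Atp2a2, 0.07 to 0.65 for Cebpb, 0.04 to 0.16 for Cited4, 0.45 to 0.85 for Acta2, -0.08 to -0.03 for Mrps24, 0.01 to 0.10 for Hrc, 0.04 to 0.33 for Ppara and -0.30 to -0.11 for Rpl13a.

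In males no gene passed for exercise either, and the calls of immediate early genes and the respiratory chain, above 0, and of fat burning genes, below 0, did not hold with an estimated correlation (adjusted p = 0.968 with an estimated correlation for each). All 24 immediate early genes lay above 0, with a median of 0.60: Klf2, a flow-responsive factor of the endothelium, was at 220 ± 39.1 CPM in exercised and 134 ± 28.7 CPM in sedentary hearts (SD, n = 3), a log2 difference of 0.71 ± 0.16 (SE), Dusp1 at 0.45 ± 0.11 and Jun at 0.62 ± 0.16. Of 48 genes of oxidative phosphorylation 37 were above 0 (0.09), with Cox4i1 at 0.31 ± 0.08 and Cyc1 at 0.29 ± 0.07. Of 27 genes of fatty acid oxidation 22 lay below 0, with a median of -0.11: Hadha was at -0.23 ± 0.08, Fabp3, the fatty acid carrier of the heart, at -0.24 ± 0.09, Decr1 at -0.23 ± 0.09 and Etfdh at -0.16 ± 0.07. Of 30 calcium handling genes 25 lay below 0 (-0.14), with Hrc, a calcium buffer of the sarcoplasmic reticulum, at -0.27 ± 0.07 and Cacna1s at -0.50 ± 0.13.

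Other called lists in males lay above 0. These were 29 of 30 ribosomal proteins (0.11), 19 of 23 cell cycle genes (0.27, Ccna2 at 0.98 ± 0.36 from 1.79 and 0.904 CPM), 16 of 21 inflammatory genes (0.63, Selp, an adhesion molecule, at 2.31 ± 0.68 from 1.89 and 0.374 CPM and Ccl2 at 0.81 ± 0.34) and 14 of 16 macrophage markers (0.25, C1qb at 0.27 ± 0.14 and Cd68 at 0.38 ± 0.20). So did 22 of 28 interferon genes (0.11, Isg15 at 0.54 ± 0.23 and Ifit2 at 0.31 ± 0.13), 20 of 26 genes of oxidative stress defence (0.06, 1 passing when adjusted over the list alone) and 15 of 16 endothelial markers (0.10, Tie1 at 0.17 ± 0.08).

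Camera with the preset correlation called 11 lists in males, 9 higher and 2 lower, and with an estimated correlation 0, since each adjusted p was then 0.968 except for calcium handling (adjusted p = 0.352 with an estimated correlation). Fry called 0. The preset adjusted p was 1.23e-10 for the immediate early genes, 1.38e-05 for oxidative phosphorylation and 6.38e-05 for ribosomal proteins, and these 3 kept their call without any 1 library. Adjusted over the list alone, 3, 2 and 0 of their members passed. Library means of the immediate early genes overlapped between groups (exact permutation p = 0.3). Fatty acid oxidation (0.00442) was lost without male exercised 2 (0.159) or 3 (0.102) or male sedentary 3 (0.108). Calcium handling (0.00525, 2 members passing when adjusted over the list alone) was lost without male exercised 3 (0.0634), and cell cycle (0.00525) without male sedentary 1 (0.105) or 3 (0.0635). Macrophage markers (0.00525) were lost without male exercised 1 (0.137) or male sedentary 3 (0.215), and inflammatory genes (0.00853) without male exercised 1 (0.0733) or 2 (0.0942) or male sedentary 1 (0.435). Oxidative stress defence (0.0219) was lost without male exercised 1 (0.0568) or 2 (0.229) or male sedentary 1 (0.203) or 2 (0.0571). Interferon genes (0.0288) were lost without male exercised 2 (0.573) or 3 (0.128) or male sedentary 1 (0.214) or 2 (0.517). Endothelial markers (0.0448) were lost without male exercised 2 (0.137) or 3 (0.18) or male sedentary 1 (0.066), 2 (0.136) or 3 (0.0904). Leaving out 1 library moved some medians in males by more than 1.5 times, with ranges from 0.32 to 0.80 for immediate early, from 0.06 to 0.13 for ribosomal, from -0.19 to -0.04 for fatty acid oxidation, from -0.14 to -0.09 for calcium handling, from 0.15 to 0.47 for cell cycle and from 0.09 to 0.40 for macrophage genes. They ran from 0.20 to 0.92 for inflammatory, 0.03 to 0.09 for oxidative stress and 0.07 to 0.26 for interferon genes. Other divisions of the 6 male libraries called at most 10 lists.

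No gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment for exercise in males: 0 of 16213, with 1271 (7.84%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.567. In 1999 genes (12.3%) the groups did not overlap, where chance gives 10%. Voom called 0. DESeq2, which adjusted over 6166 genes, called 25, 13 higher and 12 lower. The DESeq2 genes held Klf2 (0.71 ± 0.15, adjusted p = 0.0145 by DESeq2), Jun, Dusp1, Cox4i1 and Gpx1, a glutathione peroxidase (edgeR 0.39 ± 0.09), on the higher side. On the lower side they held Ppargc1a, the coactivator that drives mitochondrial genes (85.2 ± 18.9 against 135 ± 20.01 CPM, n = 3; edgeR -0.66 ± 0.18), and Lpin1, a lipid phosphatase that is also a coactivator (-0.36 ± 0.09). The 25 also held genes of smallest p by edgeR. Zfp622 (0.36 ± 0.07), Mtmr14, a lipid phosphatase of muscle (0.44 ± 0.09), Mrps24, of the mitochondrial ribosome (0.53 ± 0.11), Kti12 (0.49 ± 0.11), Msrb3, a methionine sulfoxide reductase (-0.33 ± 0.07), Bms1, of ribosome assembly (-0.29 ± 0.06), and Hand2os1, a noncoding RNA beside Hand2 (-0.47 ± 0.10), stood between 0.000107 and 0.000437 in unadjusted p by edgeR. Muc6, which DESeq2 did not call, was at -0.73 ± 0.16.

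The fixed panel in males held 1 gene, Ppargc1a, at an unadjusted p under 0.05 and 0 past the adjusted test. Nppa, Nppb, Myh7 and Acta1 were at -0.39 ± 0.42, 0.24 ± 0.44, -0.14 ± 0.25 and -0.39 ± 0.52, and Fos at 0.66 ± 0.36. Gja1 was at -0.15 ± 0.12 and Gja5 at -0.09 ± 0.15. Kcnd2, the channel of the transient outward current, was at -0.42 ± 0.20, its partner Kcnip2 at 0.19 ± 0.11 and Kcnj2 at 0.11 ± 0.30. Ryr2, Atp2a2 and Pln were at -0.04 ± 0.10, 0.08 ± 0.07 and -0.06 ± 0.09. Col1a1, Col3a1 and Postn were at 0.14 ± 0.11, -0.19 ± 0.20 and -0.19 ± 0.13, Cebpb and Cited4 at 0.82 ± 0.51 and 0.28 ± 0.24, and Pdk4 and Ucp3 at 0.28 ± 0.52 and 0.52 ± 0.61. Dbp, Per2 and Arntl were at 1.18 ± 0.81, 0.43 ± 0.43 and -0.85 ± 0.59, and Hspa1a at 0.39 ± 0.53. In males 34 of 63 gene values moved by more than 1.5 times with 1 library left out. Without a turn, they ran from -0.31 to -0.14 for Hadha, -0.34 to -0.15 for Fabp3, -0.31 to -0.13 for Decr1, -0.23 to -0.11 for Etfdh, 0.23 to 0.70 for Isg15, 0.22 to 0.46 for Ifit2, 0.17 to 0.39 for C1qb, 0.22 to 0.56 for Cd68, -0.21 to -0.09 for Gja1, -0.15 to -0.04 for Gja5, -0.59 to -0.22 for Kcnd2, 0.01 to 0.31 for Kcnip2 and 0.04 to 0.14 for Atp2a2. Others ran from 0.05 to 0.20 for Col1a1, -0.41 to -0.06 for Col3a1, -0.30 to -0.03 for Postn, 0.42 to 1.39 for Cebpb, 0.02 to 0.54 for Cited4, 0.58 to 1.79 for Dbp, 0.20 to 0.69 for Per2, -1.34 to -0.43 for Arntl, 0.25 to 0.55 for Hspa1a, 0.35 to 0.92 for Fos, 0.16 to 0.51 for Ankrd1 and -0.23 to -0.03 for Cpt2.

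Of all lists, fatty acid oxidation had the smallest p for a difference between the sexes in the exercise effect. This difference, females minus males, was above 0 for 25 of its 27 genes, with a median of 0.27. None passed over all genes, and 14 passed when adjusted over the list alone. Etfdh was at 0.28 ± 0.07 in females and -0.16 ± 0.07 in males, a difference of 0.44 ± 0.11 (SE, 3 libraries per group). In the same order, Fabp3 was at 0.22 ± 0.09 and -0.24 ± 0.09, Decr1 at 0.22 ± 0.09 and -0.23 ± 0.09, and Cpt2 at 0.30 ± 0.09 and -0.11 ± 0.09. Ppara, the nuclear receptor that drives these genes, was at 0.19 ± 0.13 and -0.50 ± 0.13, and Acat1, of ketone use, at 0.15 ± 0.06 and -0.17 ± 0.06. Vwa8 (0.28 ± 0.08 and -0.27 ± 0.08) and Fyco1, of vesicle transport (0.19 ± 0.07 and -0.28 ± 0.07), had the smallest p of the genes outside the Y chromosome.

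Smooth muscle genes had values of both signs. Acta2, smooth muscle actin, was at 0.69 ± 0.25 in females and -0.63 ± 0.25 in males, and Cnn1, calponin, differed by 1.68 ± 0.59; 4 of the 13 markers passed when adjusted over the list alone (median 0.07). The PPAR-responsive genes (12 of 19 above 0, 0.16), the citric acid cycle (18 of 22, 0.09) and calcium handling (25 of 30, 0.11, Hrc at 0.32 ± 0.10) lay above 0, with 3, 1 and 0 members passing when adjusted over the list alone. Below 0 were interferon genes (26 of 28, -0.24, Ifit2 at -0.59 ± 0.19), ribosomal proteins (29 of 30, -0.12, Rpl13a at -0.56 ± 0.19), cell cycle (21 of 23, -0.40, Ccnb1 at -1.50 ± 0.67), endoplasmic reticulum stress (18 of 21, -0.24, Sdf2l1 at -0.99 ± 0.44) and cardiac stress genes (11 of 14, -0.42, Ankrd1 at -0.85 ± 0.30 and Myh7 at -0.86 ± 0.35). Endothelial markers (13 of 16, -0.11, Tie1 at -0.29 ± 0.11) and erythroid markers (7 of 7, -4.47, Hbb-bt at -4.76 ± 2.32) did so too. Without 1 library, values ran from -1.04 to -0.51 for Myh7 and -1.27 to -0.50 for Sdf2l1.

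Camera called these 12 lists with the preset correlation. Its adjusted p was 7.45e-13 for fatty acid oxidation (adjusted p = 0.521 with an estimated correlation). It was 7e-06 for ribosomal proteins and 6.15e-05 for interferon genes (adjusted p = 0.868 with an estimated correlation for both), 0.00781 for the citric acid cycle (adjusted p = 0.521 with an estimated correlation) and 0.00781 for calcium handling (adjusted p = 0.391 with an estimated correlation). These 5 kept their call without any 1 library. The calls of cell cycle (0.00146), erythroid (0.00795), PPAR-responsive (0.00983), endoplasmic reticulum stress (0.00983), smooth muscle (0.0228), cardiac stress (0.0252) and endothelial genes (0.0428) did not hold with an estimated correlation either (adjusted p = 0.391 for smooth muscle and between adjusted p = 0.868 and adjusted p = 0.953 for the others). Fry called 0. Cell cycle and PPAR-responsive genes were lost without female exercised 1 (0.0539 for both) or female sedentary 3 (0.0896 for both), the latter also without male exercised 3 (0.0905). Erythroid genes were lost without female sedentary 1 (0.198), male exercised 1 (0.056) or male sedentary 1 (0.0527), and smooth muscle genes without male exercised 2 (0.116) or male sedentary 1 (0.0632). Cardiac stress genes were lost without female exercised 3 (0.0581), female sedentary 1 (0.198) or 3 (0.0528), male exercised 2 (0.541) or 3 (0.0827) or male sedentary 1 (0.191). Endoplasmic reticulum stress genes were lost without female exercised 2 (0.112), female sedentary 3 (0.0528), male exercised 2 (0.561) or male sedentary 1 (0.0556). Endothelial genes were lost without female exercised 2 (0.246), female sedentary 2 (0.387), male exercised 2 (0.116) or 3 (0.141) or male sedentary 1 (0.0527), 2 (0.0801) or 3 (0.0652). In the 9 libraries with few atrial transcripts the calls of the citric acid cycle (0.0623), cardiac stress (0.0699), endoplasmic reticulum stress (0.0784), endothelial (0.557) and erythroid genes (0.779) were lost, and with ranks those of PPAR-responsive (0.0682) and smooth muscle genes (0.187). Medians of the difference that moved by more than 1.5 times when 1 library was left out ran from -0.61 to -0.12 for cardiac stress, from -0.33 to -0.06 for endoplasmic reticulum stress, from -0.65 to -0.23 for cell cycle, from -0.40 to -0.20 for interferon, from -0.18 to -0.06 for ribosomal and from -0.02 to 0.36 for smooth muscle genes. They ran from 0.11 to 0.31 for PPAR-responsive and from 0.06 to 0.10 for citric acid cycle genes. Of 100 groupings of the libraries within each sex, 22 called as many lists, so the number of lists is within what these libraries give under other groupings.

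**Figure D2:**
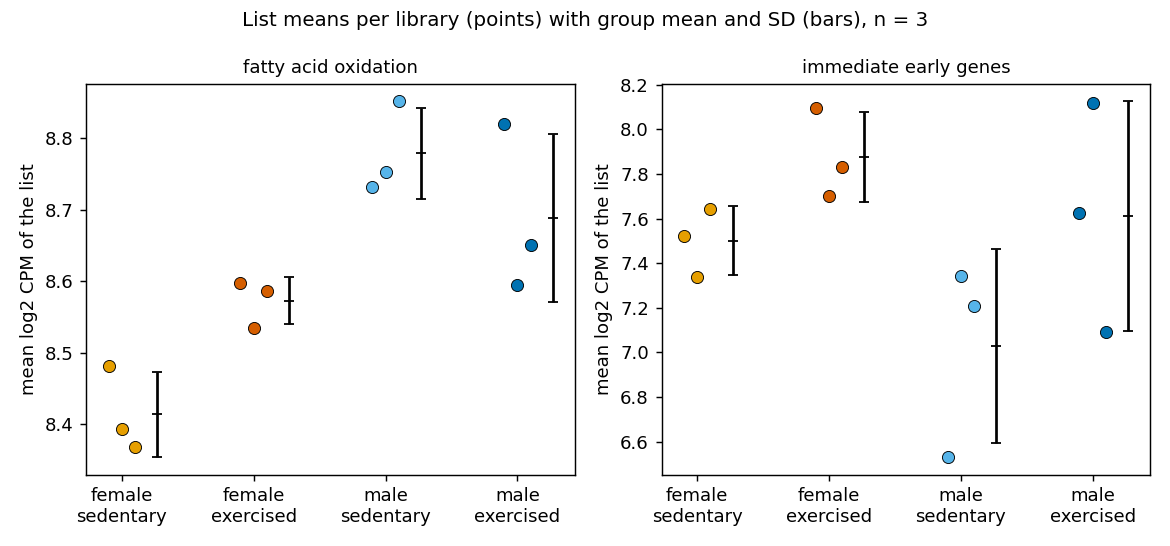
Mean log2 CPM of the fatty acid oxidation list (left) and the immediate early gene list (right) in each library (points), with group mean and SD (bars), n = 3. For fatty acid oxidation the group means are 8.41 in sedentary and 8.57 in exercised females and 8.78 and 8.69 in sedentary and exercised males.

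No gene passed for the difference between the sexes in the exercise effect by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: 0 of 16213, with 769 (4.74%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.906. Voom called 0. DESeq2, which adjusted over 4876 genes, called 10, 8 above 0 and 2 below, among them Ddx3y, Vwa8, Acta2, Fyco1 and Etfdh. The Y-linked gene rests on the traces in exercised females. Not among the 10 and below 0, Bola1 was at -0.62 ± 0.15, Sox12 at -0.72 ± 0.19, and Zfp622, Mtmr14 and Mrps24, which were at -0.05 ± 0.07, -0.02 ± 0.09 and -0.06 ± 0.11 in females, at -0.41 ± 0.10, -0.45 ± 0.12 and -0.59 ± 0.15. Eif4ebp1 was the 1 gene that passed without female exercised 3 (-1.28 ± 0.13, adjusted p = 0.00282, named after its values were seen). Across the 16213 genes, which are not independent, the exercise effects of the sexes had a Pearson correlation of 0.10, a Spearman correlation of 0.07 and a covariance of 0.0097. The sexes share no libraries. As list means per library, fatty acid oxidation and smooth muscle markers had exact permutation p of 0.025 and 0.01 for the difference between the sexes, and 0.312 and 0.25 when adjusted over the 25 measures.

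Averaged over the sexes no gene passed, and the calls of immediate early genes and the respiratory chain, above 0, and of matrix genes, below 0, did not hold with an estimated correlation (adjusted p = 0.545, adjusted p = 0.545 and adjusted p = 0.716 with an estimated correlation). All 24 immediate early genes lay above 0 (median 0.48), and 6 passed when adjusted over the list alone: Jun was at 0.51 ± 0.11, Dusp1 at 0.33 ± 0.07, Klf2 at 0.41 ± 0.11 and Egr3 at 0.71 ± 0.20 (SE, 6 exercised and 6 sedentary libraries). Of 48 genes of oxidative phosphorylation 47 lay above 0 (0.08), with 9 passing when adjusted over the list alone, Cyc1 at 0.20 ± 0.05 and Uqcrc1 at 0.15 ± 0.04. Gpx1 and Fth1, the ferritin heavy chain, were at 0.28 ± 0.06 and 0.23 ± 0.05, and 24 of 26 genes of oxidative stress defence were above 0 (0.07, 1 passing when adjusted over the list alone). Macrophage markers were above 0 in 15 of 16 (0.24, Cd68 at 0.40 ± 0.14), and inflammatory genes in 15 of 21 (0.59, Ccl2 at 0.79 ± 0.24).

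The citric acid cycle had 18 of 22 genes above 0 (0.04, Mdh2 at 0.11 ± 0.04), and the matrix list 26 of 34 below 0 (-0.07, Postn at -0.32 ± 0.09). Cardiac stress genes were below 0 in 9 of 14 (-0.12, Myh7 at -0.57 ± 0.18 and Nppa at -0.97 ± 0.29). Camera called these 8 lists, at 2.58e-15 for immediate early genes and 1.13e-12 for oxidative phosphorylation (adjusted p = 0.545 with an estimated correlation for both). Its adjusted p was 1.22e-05 for oxidative stress defence (adjusted p = 0.545 with an estimated correlation), and 5.66e-06 for macrophage markers and 5.41e-05 for inflammatory genes (adjusted p = 0.601 with an estimated correlation for both). Matrix genes had 0.00196 (adjusted p = 0.716 with an estimated correlation), the citric acid cycle 0.00498 (adjusted p = 0.545 with an estimated correlation) and cardiac stress genes 0.0488 (adjusted p = 0.97 with an estimated correlation). The first 5 kept their call without any 1 library. Matrix genes and the citric acid cycle lost theirs without male sedentary 2 (0.0969 and 0.106). The cardiac stress genes lost theirs without female exercised 3 (0.115), female sedentary 1 (0.19) or 3 (0.0735), male exercised 1 (0.442) or 3 (0.113) or male sedentary 2 (0.096) or 3 (0.161). They also lost it with the atrial score (0.0534), in the 9 libraries with few atrial transcripts (0.0562), with the RLE scaling (0.0502) and with ranks (0.0908). Leaving out 1 library moved 3 medians by more than 1.5 times, with ranges from -0.18 to -0.05 for cardiac stress, from -0.11 to -0.06 for matrix and from 0.35 to 0.70 for inflammatory genes. Lists numbered 14 without female exercised 2 and 5 without male sedentary 2, and 72 of 100 groupings within each sex called at least 8.

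No gene passed for the average by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: 0 of 16213, with 1018 (6.28%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.691. In 96 genes (0.6%) every exercised library lay on 1 side of every sedentary library of its sex, in the same direction in both, where chance gives 0.5%. Voom called 0. DESeq2, which adjusted over 2296 genes, called 14, all above 0. Among them were Jun (0.52 ± 0.11, adjusted p = 0.00305 by DESeq2), Jund (edgeR 0.68 ± 0.17), Dusp1, Klf2, Fth1, Ftl1, the ferritin light chain (edgeR 0.30 ± 0.07), Cited2 (edgeR 0.48 ± 0.11), Uqcrc1 and Atp5a1 (edgeR 0.11 ± 0.04). Jund, Ftl1, Cited2 and Atp5a1 were named after their values were seen. Jun was also the 1 gene that passed without male exercised 3 (0.60 ± 0.08, adjusted p = 0.0383). Tbx3, a factor of the conduction system, was at -0.41 ± 0.09, Cib3 at -0.96 ± 0.22, Dpysl3 at -0.30 ± 0.07, Alkbh1 at -0.34 ± 0.08 and Bms1 at -0.18 ± 0.05. In the panel of 26 genes, averages ran from -0.97 to 0.72 and 6 had an unadjusted p under 0.05.

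**Figure D3:**
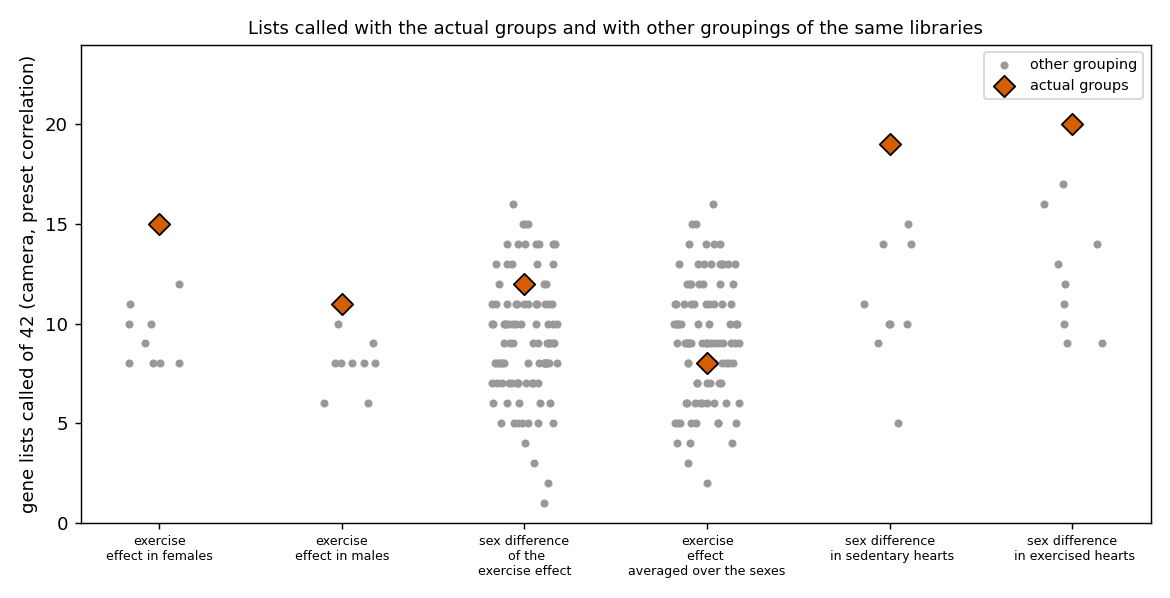
Number of gene lists called by camera with the preset correlation, of 42, for each contrast with the actual groups (diamonds) and with other groupings of the same libraries (points). The actual count lies above the other groupings in 4 contrasts (15, 11, 19 and 20 lists against at most 12, 10, 15 and 17) and among them in the other 2.

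In sedentary hearts 358 genes differed between the sexes, among them 17 of fatty acid oxidation, lower in females. Of its 27 genes 26 lay below 0 (median -0.38) and 22 passed when adjusted over the list alone (adjusted p = 0.174 with an estimated correlation). Among them were Acadm, the medium-chain acyl-CoA dehydrogenase, at 1220 ± 21.9 CPM in females and 1658 ± 68.5 CPM in males (SD, n = 3; -0.44 ± 0.05), Decr1 (-0.62 ± 0.09) and Slc25a20 (-0.65 ± 0.10). Of 22 citric acid cycle and related genes 20 lay below 0 (-0.23), with 7 passing and 14 when adjusted over the list alone (adjusted p = 0.0295 with an estimated correlation). Cs was at -0.33 ± 0.05, Acat1 at -0.41 ± 0.06 and Dlst at -0.31 ± 0.05. Interferon genes lay above 0 in 28 of 28 cases (0.51), with 9 passing and 20 when adjusted over the list alone (adjusted p = 0.19 with an estimated correlation). Among them were Irf7, the master factor of the interferon response, at 1.06 ± 0.16, Oasl2 at 0.79 ± 0.13, Ifit1 at 1.06 ± 0.23 and Ifi27l2a at 1.39 ± 0.26. Matrix genes lay above 0 in 32 of 34 (0.30), with 6 passing and 13 when adjusted over the list alone (adjusted p = 0.198 with an estimated correlation). Postn was at 0.70 ± 0.13, Lum, lumican, at 0.73 ± 0.13 and Fn1, fibronectin, at 0.53 ± 0.10.

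C7, a terminal complement component (chromosome 15, 4988762 to 5063740), stood at 5.04 ± 0.37 CPM in females and 18.9 ± 3.46 CPM in males (SD, n = 3; -1.91 ± 0.15). Hsd11b1, which regenerates active glucocorticoid (chromosome 1, 193221634 to 193264075), was at 9.82 ± 1.62 and 26.3 ± 1.16 CPM (-1.42 ± 0.15). Tmem150c (chromosome 5, 100077872 to 100159808) was at -1.20 ± 0.14, Acsl6, an acyl-CoA synthetase (chromosome 11, 54303798 to 54364756), at -0.94 ± 0.09, Ogdhl, of the oxoglutarate dehydrogenase family, at -0.86 ± 0.10 and Vwa8 (chromosome 14, 78849052 to 79202310) at -0.66 ± 0.08. Higher in females were Bgn, biglycan of the matrix (chromosome X, 73483602 to 73495933), at 256 ± 10.7 against 157 ± 10.4 CPM (0.71 ± 0.07), Col14a1 (chromosome 15, 55307750 to 55520803; 1.72 ± 0.21), Mfap4, of elastic fibres (1.32 ± 0.17), Fbln1, fibulin (0.55 ± 0.08), Phlda3 (0.95 ± 0.11) and Gli1, a factor of hedgehog signalling (1.95 ± 0.28, from 2.14 and 0.553 CPM). Their adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 1.02e-05 for C7 to 0.00425 for Gli1. Of the X-linked genes that escape silencing 7 of 7 lay above 0 and 5 passed, 7 when adjusted over the list alone (camera adjusted p = 1.75e-11; adjusted p = 0.00361 with an estimated correlation). Ddx3x was at 0.70 ± 0.08, Eif2s3x at 0.62 ± 0.07, Kdm5c at 0.66 ± 0.09 and Kdm6a at 0.70 ± 0.11, while Utp14a, also on this list, was at 0.31 ± 0.13 (adjusted p = 0.215).

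Further lists held fewer genes past the test in sedentary hearts. All 30 ribosomal proteins lay above 0 in females (0.22), with 5 passing and 23 when adjusted over the list alone, Rpl3 at 0.39 ± 0.08. Oxidative phosphorylation lay below 0 in 35 of 48 (-0.09), with 2 passing and 10 when adjusted over the list alone, Ndufs1 at -0.28 ± 0.06 and Cycs at -0.32 ± 0.07. Calcium handling lay below 0 in 21 of 30 (-0.14), with 5 passing and 7 when adjusted over the list alone, Casq2, calsequestrin, at -0.35 ± 0.06 and Cacna2d1 at -0.44 ± 0.08; its mean was 0.16, on the other side of 0. Glucose use (20 of 27 below 0, -0.06, Gys1 at -0.38 ± 0.08 and Pdhb at -0.22 ± 0.05), PPAR-responsive genes (14 of 19, -0.24) and heat shock proteins (14 of 20, -0.12, Chordc1 at -0.53 ± 0.12) had 2, 3 and 1 genes lower past the test and 6, 5 and 2 when adjusted over the list alone. Immediate early genes were above 0 in all 24 cases (0.38) with 1 passing, Dusp1 at 0.43 ± 0.11, and 3 when adjusted over the list alone. Cell cycle (21 of 23, 0.58, Ccna2 at 1.39 ± 0.35, adjusted p = 0.057), inflammatory (18 of 21, 0.45, Selp at 2.60 ± 0.67, adjusted p = 0.0717) and cardiac stress genes (11 of 14, 0.31, Nppa at 1.46 ± 0.42, adjusted p = 0.119) had 0 past the test and 1, 1 and 3 when adjusted over the list alone.

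Atrial and erythroid markers were carried by 2 of the 3 sedentary females. The former had a mean log2 CPM of 4.91 and 4.10 in female sedentary 1 and 2 and 1.95 in female sedentary 3, with 1.96 in male sedentary 2, and erythroid markers 7.22, 6.28, 1.53 and 2.03 (exact permutation p by sex = 0.2 and p = 0.3). All 9 atrial markers (median 3.02, Dkk3 at 3.02 ± 0.96, adjusted p = 0.152), all 7 erythroid markers (5.85) and all 7 valve markers (1.09) lay above 0 in sedentary females, with 0 past the test and 0, 6 and 3 when adjusted over the list alone, as did 15 of 16 macrophage (0.26, C1qb at 0.27 ± 0.14, adjusted p = 0.315, and 0.14 to 0.39 without 1 library) and 9 of 12 fibroblast markers (0.34, 1 past the test and 6 when adjusted over the list alone). With the atrial score as a covariate 80 genes passed and 67 of the 358 genes named next were among them; in the 9 libraries with few atrial transcripts, which leave 1 sedentary female, 14 passed.

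By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 358 of 16213 genes differed by sex in sedentary hearts, 138 higher and 220 lower in females, and 336 were autosomal. In 4059 genes (25%) the groups did not overlap, where chance gives 10%. The count was 106, 97 and 131 without female sedentary 1, 2 and 3, 135, 236 and 68 without male sedentary 1, 2 and 3, and 225 and 234 without female exercised 1 and 2. DESeq2 called 866, which held 352 of the 358, and voom 442, while a fit with 1 surrogate variable called 30, which held 29. Dlst and Casq2 did not pass without female sedentary 1 (adjusted p = 0.0522 and adjusted p = 0.0529). Cacna2d1, Postn, Lum, Fn1, Ifi27l2a, Ifit1, Rpl3 and Gys1 did not pass without at least 3 single libraries of the sedentary groups in turn, at up to 0.0684, 0.0818, 0.0913, 0.0762, 0.0693, 0.104, 0.0897 and 0.101. Ndufs1, Cycs, Pdhb, Dusp1 and Chordc1 did not pass without 6 or more, exercised libraries among them, at up to 0.127, 0.12, 0.151, 0.152 and 0.173. The other genes named here that passed did so without any 1 library.

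Camera with the preset correlation called 19 lists in sedentary hearts, 12 higher and 7 lower in females, and the citric acid cycle held with an estimated correlation (1.17e-10; adjusted p = 0.0295 with an estimated correlation). The others did not. Fatty acid oxidation had 3.08e-20 (adjusted p = 0.174 with an estimated correlation) and interferon genes 1.6e-13 (adjusted p = 0.19 with an estimated correlation). Camera gave ribosomal proteins 2.05e-12 (adjusted p = 0.457 with an estimated correlation), matrix genes 3.29e-08 (adjusted p = 0.198 with an estimated correlation) and calcium handling 0.0013 (adjusted p = 0.0835 with an estimated correlation). Fibroblast and valve markers had 0.000562 and 0.00419 (adjusted p = 0.466 with an estimated correlation for both), and oxidative phosphorylation, glucose use, PPAR-responsive genes, cell cycle, atrial and erythroid markers 7.08e-05, 0.00546, 0.00419, 6.55e-05, 0.00419 and 0.00109 (adjusted p = 0.52 with an estimated correlation for each). Immediate early genes had 5.03e-05 (adjusted p = 0.68 with an estimated correlation), macrophage markers and inflammatory genes 0.00983 and 0.0189 (adjusted p = 0.695 with an estimated correlation for both), heat shock proteins 0.0159 (adjusted p = 0.719 with an estimated correlation) and cardiac stress genes 0.0238 (adjusted p = 0.692 with an estimated correlation). Fry called 6. Macrophage markers were lost without female sedentary 2 (0.166) or male sedentary 3 (0.178), and PPAR-responsive genes without female sedentary 3 (0.0667). Inflammatory genes were lost without female sedentary 1 (0.0598) or 3 (0.0512) or male sedentary 1 (0.451), and heat shock proteins without female sedentary 1 (0.133) or 2 (0.0703) or male sedentary 3 (0.104). Cardiac stress genes were lost without female sedentary 1 (0.12) or 3 (0.0509) or male sedentary 1 (0.128) or 2 (0.0508). In the 9 libraries with few atrial transcripts, the calls of oxidative phosphorylation (median -0.02, 0.602), glucose use (-0.05, 0.174), inflammatory genes (0.57, 0.0741), heat shock proteins (-0.05, 0.797) and atrial (0.19, 0.602), valve (0.00, 0.602), macrophage (0.17, 0.188) and erythroid markers (0.15, 0.747) were lost. With the atrial score as a covariate, those of cardiac stress genes (0.26, 0.0548), heat shock proteins (-0.05, 0.663) and atrial (-0.01, 0.812), macrophage (0.24, 0.106), erythroid (1.75, 0.221) and valve markers (0.76, 0.0845) were lost. In sedentary hearts, leaving out 1 library moved medians by more than 1.5 times, with ranges from -0.37 to -0.06 for PPAR-responsive, from -0.11 to -0.04 for glucose use, from -0.12 to -0.06 for oxidative phosphorylation, from 0.21 to 0.53 for immediate early, from -0.17 to -0.08 for heat shock and from 0.19 to 0.73 for inflammatory genes. They ran from 0.32 to 0.74 for cell cycle and from 0.13 to 0.41 for macrophage genes. Other divisions of the 6 libraries called at most 15 lists and 0 genes.

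**Figure D4:**
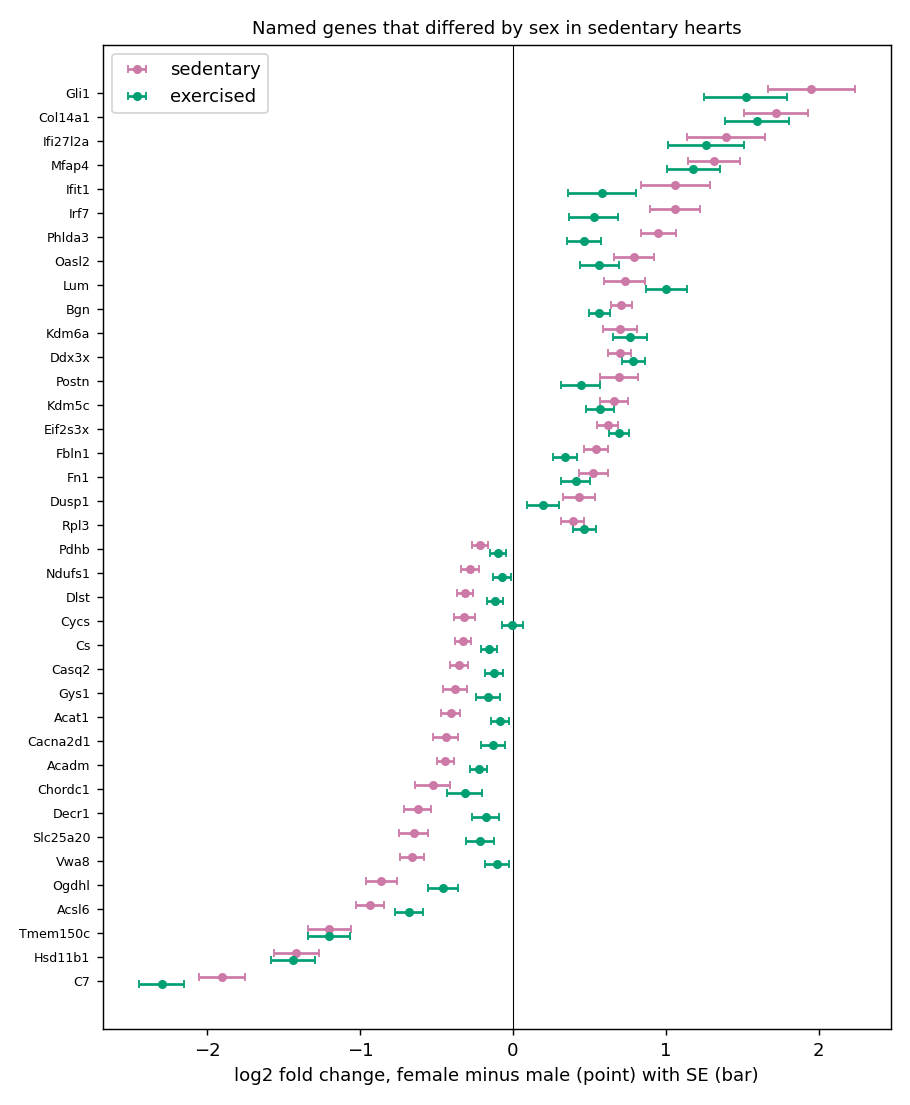
Log2 fold change, females minus males, with SE, of named genes that differed by sex in sedentary hearts, in sedentary (pink) and exercised (green) hearts, 3 libraries per group. C7 lies at -1.91 and -2.30, Bgn at 0.71 and 0.56 and Decr1 at -0.62 and -0.18.

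In exercised hearts 26 genes differed by sex, among them genes of the matrix. The test of the change in the sex difference between sedentary and exercised hearts is that of the sex difference of the exercise effect, which 0 genes passed. Lum stood at 85.9 ± 8.88 CPM in females and 42.8 ± 9.29 CPM in males (SD, n = 3; 1.00 ± 0.13), Bgn at 232 ± 12.7 and 157 ± 5.92 CPM (0.56 ± 0.07), Col14a1 at 1.60 ± 0.21, Mfap4 at 1.18 ± 0.17 and Adamtsl2, a matrix protein that binds fibrillin (chromosome 2, 27079379 to 27108981), at 1.45 ± 0.19. Of 34 matrix genes 31 lay above 0 (0.28), with 2 passing and 10 when adjusted over the list alone, and 1 lower. Of 12 fibroblast markers 12 lay above 0 (0.30), with 2 passing and 6 when adjusted over the list alone, Serpinf1 at 0.65 ± 0.12. Lower in females were C7 (5.33 ± 0.47 against 26.3 ± 3.92 CPM, n = 3; -2.30 ± 0.15), Hsd11b1 (-1.44 ± 0.14), Tmem150c (-1.21 ± 0.14), Acsl6 (-0.68 ± 0.09), Cnmd, chondromodulin (-2.29 ± 0.39, from 0.567 and 2.76 CPM) and Sox12 (-0.75 ± 0.14). Fatty acid oxidation lay below 0 in 25 of 27 (-0.10), with 1 passing and 3 when adjusted over the list alone, Acadm at -0.23 ± 0.05 (adjusted p = 0.152). Rpl3 was at 0.47 ± 0.08, and 28 of 30 ribosomal proteins lay above 0 (0.07), with 1 passing, also when adjusted over the list alone.

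The other called lists had no member past the test in exercised hearts. Interferon genes lay above 0 in 26 of 28 (0.26), with 3 when adjusted over the list alone, Ifi27l2a at 1.26 ± 0.25 (adjusted p = 0.108), Oasl2 at 0.57 ± 0.13 and Irf7 at 0.53 ± 0.16. The citric acid cycle lay below 0 in 22 of 22 (-0.12, 1 when adjusted over the list alone, Bckdha at -0.28 ± 0.06), oxidative phosphorylation in 47 of 48 (-0.10, Uqcrc1 at -0.18 ± 0.06), sarcomere genes in 21 of 26 (-0.08, Mybpc3 at -0.32 ± 0.09), heat shock proteins in 18 of 20 (-0.17, Fkbp4 at -0.23 ± 0.07) and endoplasmic reticulum stress genes in 18 of 21 (-0.12). Above 0 were glucocorticoid-responsive genes (17 of 20, 0.30, Fkbp5 at 1.16 ± 0.30), lipid synthesis (18 of 22, 0.14, Scd1 at 1.40 ± 0.56), inflammatory genes (17 of 21, 0.24), immediate early genes (20 of 24, 0.21), smooth muscle (8 of 13, 0.06, 4 when adjusted over the list alone, Acta2 at 1.48 ± 0.25, adjusted p = 0.0803) and macrophage markers (15 of 16, 0.26, 1 when adjusted over the list alone, Lyve1 at 0.72 ± 0.19). So were 8 of 9 atrial (3.12, Dkk3 at 3.12 ± 0.97), 7 of 8 adipocyte (3.89, Cfd at 4.95 ± 1.77), all 10 mesothelial (0.71) and all 7 valve markers (0.84). Without female exercised 2 the atrial median was 0.20 and the adipocyte median 0.88. Over the fits without 1 library, values ran from -0.40 to -0.21 for Mybpc3, 0.25 to 1.76 for Scd1, 1.80 to 6.02 for Cfd and -0.25 to -0.10 for Decr1.

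By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 26 of 16213 genes differed by sex in exercised hearts, 15 higher and 11 lower in females, and 15 were autosomal. The 5 X-linked genes that escape silencing and passed, 6 when adjusted over the list alone, held Ddx3x (0.79 ± 0.08), Eif2s3x (0.70 ± 0.07), Kdm6a (0.76 ± 0.11) and Kdm5c (0.57 ± 0.09), with Utp14a at 0.05 ± 0.13. In 2323 genes (14.3%) the groups did not overlap, where chance gives 10%. The count was 17 without male exercised 3 and 55 without male exercised 1, 22 with the atrial score as a covariate and 24 in the 9 libraries with few atrial transcripts. DESeq2 called 167, which held 25 of the 26, and voom 22, while fits with 1 surrogate variable and of only the groups compared called 15 each, of which 14 were shared. Adamtsl2 was lost without male exercised 2 (adjusted p = 0.0839), Mfap4 without male exercised 2 or 3 (up to adjusted p = 0.0649), Kdm5c without female exercised 1, female exercised 2 or male exercised 3 (up to adjusted p = 0.0952), and Rpl3, Cnmd, Sox12 and Serpinf1 without 4 or more libraries in turn, at up to 0.108, 0.11, 0.212 and 0.175. The other genes named here that passed did so without any 1 library.

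Camera with the preset correlation called 20 lists in exercised hearts, 14 higher and 6 lower, and 0 with an estimated correlation; fry called 4. The smallest were matrix at 9.51e-08 (adjusted p = 0.258 with an estimated correlation) and oxidative phosphorylation at 3.88e-07 (adjusted p = 0.494 with an estimated correlation). Next came the citric acid cycle at 5.96e-07 (adjusted p = 0.105 with an estimated correlation), fibroblast markers at 6.38e-07 (adjusted p = 0.258 with an estimated correlation), interferon genes at 1.12e-06 (adjusted p = 0.494 with an estimated correlation) and fatty acid oxidation at 7.92e-06 (adjusted p = 0.551 with an estimated correlation). These 6 kept their call without any 1 library. The other 14 lay between 0.0016 and 0.0445 (between adjusted p = 0.258 and adjusted p = 0.587 with an estimated correlation). Without female exercised 1, the calls of glucocorticoid-responsive genes (0.178), valve markers (0.324), immediate early (0.107), inflammatory (0.0849), ribosomal (0.0693) and endoplasmic reticulum stress genes (0.0584) were lost. Without female exercised 2, those of atrial (0.301) and adipocyte markers (0.467) and endoplasmic reticulum stress genes (0.301) were lost, and without female exercised 3 those of sarcomere (0.113), smooth muscle (0.0516) and glucocorticoid-responsive genes (0.0506). Without male exercised 2, the calls of heat shock (0.119), mesothelial (0.0877), sarcomere (0.624), smooth muscle (0.124), adipocyte (0.137), valve (0.0529) and endoplasmic reticulum stress genes (0.719) were lost. Without male exercised 3, those of macrophage (0.134) and valve markers (0.107), lipid synthesis (0.0724), ribosomal (0.0625), immediate early (0.964) and inflammatory genes (0.286) were lost. The endoplasmic reticulum stress call was also lost without male sedentary 2 (0.0515) or 3 (0.051). With the atrial score as a covariate, the calls of heat shock (-0.08, 0.355), endoplasmic reticulum stress (-0.08, 0.463), atrial (-0.05, 0.613), adipocyte (-0.15, 0.429) and valve genes (0.18, 0.414) were lost. So were those of endoplasmic reticulum stress (-0.10, 0.347) and adipocyte genes (0.77, 0.457) in the 9 libraries with few atrial transcripts, and that of smooth muscle with ranks (0.0986). In exercised hearts, leaving out 1 library moved medians by more than 1.5 times, with ranges from -0.13 to -0.04 for fatty acid oxidation, from 0.17 to 0.33 for matrix, from 0.16 to 0.41 for interferon, from -0.13 to -0.02 for sarcomere, from -0.01 to 0.48 for immediate early and from -0.24 to -0.08 for heat shock genes. They ran from -0.19 to -0.01 for endoplasmic reticulum stress, from 0.09 to 0.48 for glucocorticoid-responsive, from 0.11 to 0.38 for inflammatory, from 0.04 to 0.12 for ribosomal, from 0.06 to 0.16 for smooth muscle and from 0.14 to 0.36 for macrophage genes. They ran from 0.20 to 3.61 for atrial, 0.88 to 4.77 for adipocyte and 0.13 to 1.02 for valve genes. Other divisions of the 6 libraries called at most 17 lists and 1 gene.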

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

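The tests of Y-linked counts, of a normalization offset and of the number of genes with the atrial score were chosen after the values they measure had been seen, the fits with the atrial score and of 9 libraries after the group comparisons, and the test over all lists after that of the 1 list. For the difference of the exercise effect, females minus males, camera called 12 lists with the preset correlation and 0 with an estimated one, and 22 of 100 groupings called as many, so chance is not excluded. The median differences on the log2 scale were 0.266 for fatty acid oxidation, 0.159 for PPAR-responsive genes, 0.086 for the citric acid cycle, 0.109 for calcium handling and 0.069 for smooth muscle markers. They were -0.415 for cardiac stress genes, -0.238 for endoplasmic reticulum stress, -0.237 for interferon genes, -0.396 for the cell cycle, -0.12 for ribosomal proteins, -0.108 for endothelial markers and -4.472 for erythroid markers. Rows that the filter removed held a signal in 1 library: the mitochondrial genome took 27.3% of the counts of female sedentary 2, with 3095729 counts for mt-Co1, and 0 in the other 11. Groups of 3 libraries are too small for a test of single samples that lie apart.

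Fatty acid oxidation had opposite differences in the 2 sexes, but male library means overlapped (exact permutation p = 0.3). The median difference between the sexes was 0.27. With the atrial score as a covariate that median was 0.991 of its value without it, which argues against the atrial transcripts of 3 female libraries as the whole cause. The median of all tested genes was -0.0131 of the list's, but scaling sets the former near 0, so this test is void and an offset of normalization stays open. As large a median came from 2 of 100 groupings within each sex (0.266 against at most 0.312), but the list was taken up after its values were seen, and the smallest p of any list was matched in 13 of 100 (at most 20.447 as -log10 p), so chance is not excluded. A sex-dependent response to exercise may be behind it. A repeat in both sexes with more animals, ventricles free of atria and this list fixed in advance would test this hypothesis.

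In sedentary hearts 358 genes differed by sex, and 26 in exercised hearts. The called genes had a median difference of 0.448 (median SE 0.089), and of 0.453 (0.109) with the atrial score, a ratio of 1.01. Atrial content varied in sedentary females, so genes that follow it were hard to call. The ratio decides nothing, and atrial transcripts stay open, also for gene numbers. With the score, sedentary and exercised hearts had 80 and 22, a difference of 58 against 332. Of 100 groupings within each sex, 7 gave as large a difference in counts (up to 641), so chance is not excluded. Why the numbers fell was not tested, and since the 358 were chosen for their size in sedentary hearts, their median of 0.196 in exercised ones cannot show a narrowing.

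Y-linked genes had 108 counts in exercised and 18 in sedentary females: 54 and 6 for Ddx3y, 30 and 4 for Eif2s3y, 7 and 7 for Kdm5d, 17 and 1 for Uty. Exercised females held 85.7% of these counts and 51.2% of those of the X-linked copies (exact binomial p = 4.92e-16, for counting error alone), and in single libraries the counts were 0.175% to 0.276% of the copies' against 0.0198% to 0.0817%. This argues against reads of the X-linked copies as the source of the excess, though not for Kdm5d. Male RNA or reads carried over into the exercised female libraries might be the source: the counts per library, 0.622% to 1.02% of those in males over the 4 genes, did not differ beyond counting error (permutation p = 0.331). That explanation stays open, because Kdm5d has 7 counts, too few for the test as it was set, and no biological explanation was tested.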

How the results depend on the processing

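The 4 added settings were chosen after the data were seen. Of 8152 values of named genes and lists under other settings, 7465 kept their direction and their side of the threshold, 457 lost a call, 156 gained one and 74 turned. No called gene turned. For counts of genes, in the order females, males, sex difference of the exercise effect, average, sex in sedentary and sex in exercised hearts, DESeq2 gave 1, 25, 10, 14, 866 and 167, and the cause was not tested. Without a filter the same fit as in the report gave 357, 327, 173, 399, 1317 and 531. There the prior degrees of freedom became infinite, against 6.15, and the spread assigned to Hbb-bs went from 127 to 0.395, so these counts come from a fit that broke down. Without the mitochondrial rows it still gave 328, 357, 191, 412, 1326 and 556. With total counts of at least 5, 10, 20 or 50 it gave 0 in the 4 exercise contrasts and 364 and 33, 329 and 27, 324 and 26, or 335 and 26 in the sex contrasts, which points to genes of very low count. The bias-adjusted test without a filter gave 0, 0, 0, 0, 370 and 43, and 404 and 48 in the sex contrasts without the mitochondrial rows. For sex in sedentary hearts 1 surrogate variable gave 30, an adjusted p of 0.1 gave 816, the atrial score 80 and the 9 libraries 14, which has fewer samples. For sex in exercised hearts 1 surrogate variable gave 15, an adjusted p of 0.1 gave 41 and a fit of only the groups compared 15, with fewer samples. With 1 library left out, the counts of genes ran from 0 to 1, 0 to 0, 0 to 1, 0 to 1, 68 to 462 and 17 to 55. Lists called ran from 11 to 18, 7 to 12, 9 to 13, 5 to 14, 17 to 19 and 13 to 22. With an estimated correlation they were 0, 0, 0, 0, 1 and 0, and the cause was not tested. With 9 libraries, 13 lists were called for the average and 12 for sex in sedentary hearts; the cause was not tested.

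These values turned, and the causes were not tested. For lists, the 9 libraries gave medians of -0.22 for erythroid and 1.029 for valve markers in females, -0.87 for erythroid markers in the sex difference of the exercise effect, and -0.049 for heat shock proteins and 0.151 for erythroid markers by sex in sedentary hearts. Where the median kept its sign, it was the direction of the list test that turned. The atrial score gave -0.01 and -0.049 for atrial markers by sex in sedentary and exercised hearts and -0.149 for adipocyte markers in exercised ones. With 1 library left out, ribosomal proteins in females ran from -0.098 to 0.027 (without female sedentary 3). By sex in exercised hearts endoplasmic reticulum stress ran from -0.191 to -0.011 (without male exercised 2) and immediate early genes from -0.013 (without male exercised 3) to 0.482. In females the 9 libraries gave 2.386 for Chad, 0.776 for Acta1, -0.013 for Kcnip2, -0.121 for Pln, 0.055 for Col1a1, 0.017 for Ppargc1a, 0.005 for Arntl, 0.08 for Mtmr14 and -0.011 for Hrc. Voom gave 0.033 for Gja1, -0.052 for Ucp3 and 0.414 for Hspa1a, 1 surrogate variable 0.0 for Kcnip2 and 0.12 for Hspa1a, and the atrial score 0.05 for Hspa1a. With 1 library left out, values in females ran from -0.416 to 0.27 for Acta1, -0.475 to 0.201 for Arntl, -0.208 to 0.035 for Col1a1, -0.288 to 0.113 for Col3a1, -0.503 to 0.983 for Dbp, -0.157 to 0.137 for Gja1 and -0.028 to 0.229 for Gja5. They ran from -0.399 to 0.925 for Hspa1a, -0.023 to 0.044 for Kcnip2, -0.112 to 0.322 for Kcnj2, -0.085 to 0.015 for Mtmr14, -0.135 to 0.592 for Pdk4 and -0.666 to 0.307 for Per2. For Pln they ran from -0.044 to 0.099, for Ppargc1a from -0.178 to 0.094 and for Ucp3 from -0.246 to 0.362. In males voom gave -0.131 for Nppb. With 1 library left out, values in males ran from -0.732 to 0.01 for Acta1, -0.134 to 0.315 for Kcnj2, -0.489 to 0.035 for Myh7, -0.63 to 0.158 for Nppa, -0.254 to 0.61 for Nppb and -0.014 to 0.616 for Pdk4. They ran from -0.115 to 0.039 for Pln, -0.094 to 0.063 for Ryr2 and -0.501 to 0.855 for Ucp3. Utp14a by sex in exercised hearts ran from -0.031 to 0.101. Depth limits Y-linked genes in females and genes near 1 CPM such as Fgf6, Selp and Cnmd.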

Other observations

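The tests given here were set before their results were seen. Several gene groups of the trained heart were called in neither sex. Circadian clock genes had a median of 0.05 in females and 0.25 in males (camera adjusted p = 0.893 and adjusted p = 0.275), and genes of exercise-associated growth signalling -0.01 and 0.10 (0.893 and 0.462). Potassium channels stood at 0.02 and 0.05 (0.308 and 0.97), sodium channels and connexins at -0.03 and 0.03 (0.893 and 0.845), and sarcomere and Z-disc genes at -0.01 and 0.01 (0.893 and 0.97). Glucose use was at 0.04 and 0.01 (0.113 and 0.845), and angiogenesis and hypoxia at -0.02 and 0.05 (0.946 and 0.532). Genes of protein and mitochondrial turnover were above 0 in 17 of 20 cases in females (0.08) and in 12 of 20 in males (0.05), with 0.143 and 0.508. Mesothelial markers lay below 0 in 9 of 10 cases in males (-0.46, 0.0734) and in 8 of 10 in females (-0.08, 0.893). These values were not shown to be equal to 0.

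Other groupings of the libraries were run for every count. Splits of 6 libraries number 10, too few for a share under 0.05. For genes they gave 0 in females with the real groups and at most 0 otherwise (10 of 10 splits as large), 0 and at most 2 in males (10 of 10), 358 and at most 0 by sex in sedentary hearts (1 of 10), and 26 and at most 1 in exercised hearts (1 of 10). For lists they gave 15 and at most 12, 11 and at most 10, 19 and at most 15, and 20 and at most 17. For the sex difference of the exercise effect and the average, the 12 and 8 lists were matched by 22 and 72 of 100 groupings (at most 16 in both), so chance is not excluded. A count of 0 genes is matched by any grouping (100 of 100, at most 20), which decides nothing. A correlation of exercise effects between the sexes as high as 0.10 came from 10 of 100 groupings (at most 0.238), and chance is not excluded there either. Each other split of 6 libraries sets 2 libraries of a group against 1, so it keeps part of the real difference.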
